A study of Rattus norvegicus with 18 samples.

How the data were processed

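Messenger RNA was measured in cultured rat hippocampal neurons on 18 Affymetrix arrays, 3 in each of 6 groups. Per the labels' protocols, the cells received lentivirus carrying control or MEF2-specific shRNAs on day 3 of culture. On day 10 they were given AP5 and TTX for 1 h and then 55 mM KCl for 0, 1 or 6 h. The labels give total RNA as the starting material, a Qiagen RNeasy Micro kit for its extraction, and biotin-labelled cRNA made by Affymetrix procedures.

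The deposited table holds 1 intensity per probe set and array, on a linear scale. A probe set is a group of short oligonucleotides read out as 1 value. How probes were combined and how arrays were normalized is not given in the sources used here. The arrays were on a common scale as deposited, with medians of 240 to 248, maxima of 23233 to 24868 and 40th percentiles of 154 to 164. No array of the table was left out, and no 2 arrays held identical values. The number of arrays per group, 3, limits the precision of every comparison. Of the 31099 probe sets, 20832 carried 1 gene symbol in the platform annotation, 436 carried several and 9831 were not listed with a gene there. Of the probe sets with 1 symbol, 20764 matched a gene of the RefSeq table of assembly GRCr8, which was used for names alone and changed no symbol. No genome sequence or probe position was used here, so genes are given without coordinates.

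Values under the table's 20th percentile, a signal of 72.6, were raised to it, and log2 was taken. Fold changes of dim genes are therefore understated, and where every array of a group lay at this floor the fold is a lower bound, written as "at least". Each gene was represented by the probe set with the highest mean over the 18 arrays, among probe sets with 1 symbol. Of 14218 genes, 4526 had more than 1 probe set. Genes were tested where that probe set exceeded the 40th percentile of its own array on at least 3 arrays, which left 10933 genes. Other probe sets are given for some of the named genes.

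Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 18 arrays with 1 mean per group, which left 12 residual degrees of freedom. P-values are two-sided with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. The comparisons were 1 h and 6 h of KCl against 0 h within each arm, 6 h against 1 h in the control arm, RNAi against control at each time and averaged over the 3 times, and the interaction of RNAi with KCl at 1 h and at 6 h. The interaction is the KCl response of the RNAi arm minus that of the control arm. Standard errors of log2 fold changes come from these fits, and n is 3 arrays per group throughout.

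A total of 24 gene lists were fixed beforehand from general knowledge of neurons, of MEF2 and of the cell types that such cultures can hold. Each was tested with limma's camera, a competitive test of a list against all other genes, at a preset correlation of 0.01 between genes, adjusted over the 24 lists. Calls were also computed with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. Counts over a list are given as called over all genes tested and as adjusted over the list alone. In the order of the results, the lists are immediate early transcription factors, reported MEF2 targets, activity-regulated synaptic effectors, MAP kinase phosphatases and feedback inhibitors, endoplasmic reticulum stress and heat shock, cholesterol biosynthesis, glutamate receptors and excitatory scaffolds, apoptosis and p53 response, secreted factors and neuropeptides, MEF2 family and class IIa histone deacetylases, voltage-gated potassium channels, voltage-gated sodium and calcium channels, GABA receptors and inhibitory synapse, synaptic vesicle proteins, circadian clock, glycolysis and glucose uptake, interferon response, housekeeping controls, proliferating and progenitor cell markers, and markers of neurons, astrocytes, oligodendrocyte lineage, microglia and macrophages, and endothelial cells and fibroblasts. Some lists share members, so their calls are not separate results. Reported MEF2 targets share Nr4a1, Jun and Klf4, among others, with the immediate early list, Arc with the synaptic effectors and Bdnf with the secreted factors. Overlaps between calls were tested with Fisher's exact test, two-sided.

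Named genes followed a rule. In each comparison these are the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups compared, which chance gives for 10% of genes with 3 arrays against 3. No such condition applied to interactions and averages, and symbols starting with LOC or RGD were passed over. Mef2a, Mef2c, Mef2d, Fos, Npas4, Egr1, Nr4a1, Arc, Bdnf, Homer1 and Jun were always included, as were up to 4 members of each list with the smallest adjusted p and the 15 largest RNAi differences among genes induced by KCl and lower with RNAi at each time. Npas4 was not analysed here, a further gene fixed with these is not reported here, and Mef2b, Egr3 and Ptgs2 were too dim to be tested.

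Replicate numbers were checked for pairing. All 45 pairs of arrays of the same number from different groups had correlated deviations from their group means (Pearson r across genes of 0.168 to 0.741, median 0.491). In 43 of these pairs the array of the first group correlated best with its own number in the other group. A fit with the replicate number as a block, with 10 residual degrees of freedom, was therefore set beside the comparisons where it changed a call or moved a count more than 1.5 times. The pairing comes from the data, since the labels do not say what a number shares.

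Other alternatives were quantile normalization, log2 of the value plus the 20th percentile, no filter on dim probe sets, a stricter filter at the 60th percentile, all probe sets, an intensity trend with a robust prior, array weights, a fit to only the groups compared, leaving out each array in turn, and, for overlaps, the KCl response taken from both arms. Leaving out the 6 arrays of number 1 was added after the data were seen. The model was tested on simulated arrays of 10933 genes with 100 genes changed at each size. At 6 h between arms it recovered 90% of 1.5-fold and 98% of 2-fold changes with 10 false calls. For 1 h against 0 h it recovered 88% and 96% with 8 false calls, and for the interaction at 6 h it recovered 68% and 93% with 7 false calls. These arrays were drawn independently for each gene and array. The rates need not hold for the real arrays, where genes and arrays of the same number correlate and many more genes were called.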

Results

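The data are 18 gene expression arrays of rat hippocampal neurons grown in dissociated culture, 3 for each of 6 groups. Neurons carried lentiviral control shRNAs (the control arm) or shRNAs against MEF2 (the RNAi arm), and RNA was taken after 0, 1 or 6 h in 55 mM KCl, which depolarizes the cell membrane and opens calcium channels. AP5, which blocks NMDA receptors, and TTX, which blocks voltage-gated sodium channels, were on the cells for 1 h before KCl, so the 0 h arrays come from neurons kept in these blockers. MEF2 proteins are transcription factors that bind regulatory DNA of activity-induced genes and are switched by calcium signals. The labels call the arrays biological replicates and describe the cultures no further. The stated purpose was to find genes that respond to activity under the control of MEF2. Arrays of the same group correlated at 0.987 to 0.996 across probe sets, and 10933 genes were tested.

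Knockdown was examined first. Mef2a was lower in every RNAi array than in every control array, with log2 signals of 8.79 to 9.28 in the RNAi arm and 10.58 to 11.19 in the control arm. Mean Mef2a signals were 1843, 2164 and 1749 at 0, 1 and 6 h in the control arm and 604, 573 and 482 in the RNAi arm. This left 32.8%, 26.5% and 27.6% of the control level, log2 differences of -1.61, -1.92 and -1.86 (SE 0.10, n = 3 arrays per group; adjusted p = 1.17e-07, 2.12e-08 and 3.08e-08). All 4 Mef2a probe sets were called lower at all 3 times, the weakest at 67.8%, 55.1% and 66.2% of control. Mef2d fell less, to 69.5%, 74.7% and 67.5% of control by the brighter of its probe sets (log2 differences -0.52, -0.42 and -0.57, SE 0.08; adjusted p = 0.000283, 0.00138 and 0.000152). Its log2 signals were 8.05 to 8.22 against 8.57 to 8.73 at 0 h, 8.20 to 8.40 against 8.68 to 8.73 at 1 h and 8.40 to 8.60 against 9.02 to 9.21 at 6 h, without overlap between arms. The other Mef2d probe set was not called, with differences of -0.14, 0.00 and -0.08. Mef2c differed by -0.18, -0.38 and -0.30 (SE 0.13; adjusted p = 0.423, 0.0562 and 0.135) and was not called at any time, although it was called over the average of the times (-0.29, adjusted p = 0.00697). With the replicate block, Mef2c was called at 1 h (adjusted p = 0.000663, range over its alternatives 0.000663 to 0.251) and at 6 h (adjusted p = 0.00395, range 0.00395 to 0.422), and without RNAi 1 h replicate 3 its adjusted p at 1 h was 0.0474.

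**Figure D1:**
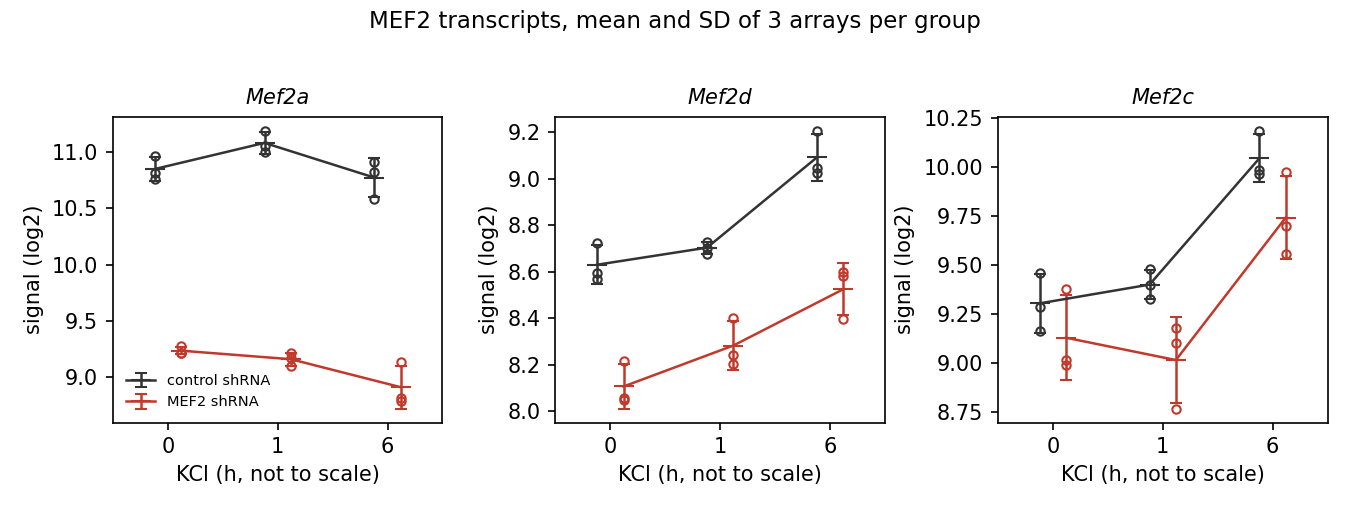
Log2 signal of Mef2a, Mef2c and Mef2d in each of the 18 arrays by hours of KCl and by arm, with points for arrays and bars for group means. Mef2a lies between 8.79 and 9.28 in the RNAi arm and between 10.58 and 11.19 in the control arm.

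The first comparison asked which genes respond to 1 h of KCl in neurons with control shRNAs. The largest rises were mostly of transcription factors of the immediate early class, which need no new protein synthesis to be transcribed. Fosb rose 33.4-fold (log2 5.06, SE 0.19, n = 3 per group; adjusted p = 7.39e-11), Egr4 20.1-fold (SE 0.17) and Fos 19.7-fold (SE 0.35 on the log2 scale), although a second, dimmer Fos probe set was flat at 0.08. Junb rose 15.7-fold, the nuclear receptors Nr4a1 and Nr4a2 rose 10.2-fold and 9.78-fold, and Egr2 and Egr1 rose 7.69-fold and 7.33-fold. Arc, whose protein acts in the postsynaptic trafficking of AMPA receptors, rose 8.09-fold (log2 3.02, SE 0.12; adjusted p = 1.37e-10), and Ccn1, a secreted matrix protein, rose 10.6-fold. Among feedback inhibitors of signalling, the MAP kinase phosphatase Dusp1 rose 7.49-fold (SE 0.10, with its other probe set at 3.69 on the log2 scale), Dusp5 rose by 1.49 on the log2 scale, and Rgs2, which limits G protein signalling, rose 3.21-fold. Bdnf, the neurotrophin, rose 2.03-fold (log2 1.02, SE 0.16; adjusted p = 0.0016), with its other probe set at 0.23 and not called. Homer1 was flat by its brightest probe set (-0.06, SE 0.07; adjusted p = 0.865), but another of its probe sets rose by 3.10 on the log2 scale. Fewer genes fell far, led by Txnip, an inhibitor of thioredoxin that responds to glucose, which fell 4.83-fold (log2 -2.27, SE 0.24; adjusted p = 2.26e-05). The clock repressor Bhlhe40 fell 2.27-fold, and the zinc-finger genes Rbak, Zfp157 and Zfp12 changed by -1.06, -0.90 and -0.82. Over all genes, 130 were called higher and 165 lower, of which 40 and 5 changed at least 2-fold, and 1288 genes had an unadjusted p under 0.05. The replicate block called 235 higher and 366 lower, 601 in all, and without control 0 h replicate 2 the count of 295 became 188.

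By list, 20 of the 25 immediate early transcription factors measured rose at 1 h (20 rose and 1 fell adjusted over the list alone), with a median log2 change of 1.95 (camera adjusted p = 2.37e-64). Of 15 activity-regulated synaptic effectors, 6 rose (8 adjusted over the list alone; camera adjusted p = 1.67e-17), including Arc, Rgs2 and the growth arrest genes Gadd45g and Gadd45b, at 2.33 and 1.66. Among 14 MAP kinase phosphatases and feedback inhibitors, 6 rose (7 adjusted over the list alone; adjusted p = 1.04e-11), including Dusp1, Dusp5 and the EGF receptor inhibitor Errfi1 at 0.85. The list of reported MEF2 targets had 6 of 14 members higher (7 adjusted over the list alone; adjusted p = 2.05e-12), among them Nr4a1, Arc, Klf4 at 2.72 and Jun at 1.31. Its members may have been picked on these samples, so its direction is not independent evidence. Nr4a1, Klf4 and Jun are also in the immediate early list and Arc is among the synaptic effectors, so these calls partly repeat one another. These 4 lists were also called with an estimated correlation. For 4 more lists the call was lost with it. Endoplasmic reticulum stress and heat shock genes had 4 of 15 higher (5 higher and 2 lower adjusted over the list alone; adjusted p = 0.0162, and adjusted p = 0.35 with an estimated correlation), led by Herpud1 at 0.72, which takes part in degradation of misfolded proteins. Cholesterol biosynthesis had 1 of 13 higher, Idi1 at 0.48 (2 adjusted over the list alone; adjusted p = 0.00499, and adjusted p = 0.676 with an estimated correlation). Glutamate receptors and excitatory scaffolds (25 members, median 0.07) and apoptosis and p53 response genes (10 members, median -0.18) had no member called over all genes, and 1 higher and 1 lower in turn adjusted over the list alone. Their adjusted p values were 0.0099 and 0.0356, and with an estimated correlation adjusted p = 0.676 and adjusted p = 0.35.

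The calls of these 4 lists also rested on single arrays. Without control 0 h replicate 1 the adjusted p was 0.355 for glutamate receptors and excitatory scaffolds and 0.133 for endoplasmic reticulum stress, and without control 1 h replicate 3 it was 0.131 and 0.0598. Cholesterol biosynthesis had an adjusted p of 0.103 without control 0 h replicate 3. Apoptosis and p53 response genes had 0.0654 without control 1 h replicate 1, 0.0504 without control 0 h replicate 2, 0.0659 without control 0 h replicate 3 and 0.112 without control 1 h replicate 3.

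After 6 h of KCl many more genes were called in the control arm. Bdnf had risen 10.7-fold (log2 3.42, SE 0.16, n = 3 per group; adjusted p = 1.15e-09), and by 1.22 on its other probe set, and the plasminogen activator inhibitor Serpinb2, at the floor in every 0 h and 1 h array, was at least 17.4-fold higher (adjusted p = 1.19e-11). Tchh, which encodes trichohyalin, rose 9.56-fold (SE 0.25), Crem, a cAMP-responsive repressor, rose 7.09-fold (all 4 of its other probe sets also rose, the least by 0.73 on the log2 scale), and Gem, a small GTPase that restrains calcium channels, rose 6.45-fold. Fosb, Fos and Junb were still 14.9-fold, 13.9-fold and 2.93 log2 units above 0 h, while the second Fos probe set was at 0.15. Rgs2 stood at 5.71-fold, Nr4a1 at 5.43-fold and Egr4 at 6.93-fold. Neuropeptide and granule genes were among those that rose, with Vgf 2.92-fold (SE 0.17), Nppc at 1.31 on the log2 scale and Scg2 2.3-fold. The period genes Per1 and Per2 rose by 1.27 and 0.88, and the class IIa histone deacetylase Hdac5, a repressor of MEF2, rose 2.4-fold (SE 0.09). Mef2c and Mef2d were 1.67-fold and 1.38-fold higher (adjusted p = 0.00028 for Mef2c), whereas Mef2a was at -0.08 (adjusted p = 0.59). Another Mef2a probe set was called higher, at 0.48, and the other Mef2d probe set, at 0.09, was not called. Homer1 rose by 0.24 on the brightest probe set and by 3.39 and 3.10 on a pair of others. The leading falls were of the arrestin-like genes Arrdc4, 6.59-fold (log2 -2.72, SE 0.13; adjusted p = 1.15e-09), and Arrdc3, 4.3-fold, and of Txnip, 6.22-fold. Zc3h6, at the floor after 6 h, was at least 4.39-fold lower, Nr3c2, the mineralocorticoid receptor, fell 3.62-fold, and Fst, an activin antagonist, was at -1.91. Arpp21 fell by 1.73 on the log2 scale on its brighter probe set and rose by 1.41 on the other. In all, 1759 genes were called higher and 2783 lower, with 182 and 165 changed at least 2-fold.

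The immediate early transcription factors had 21 of 25 members higher at 6 h (21 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.34e-15, and adjusted p = 0.0608 with an estimated correlation). Activity-regulated synaptic effectors had 12 of 15 higher (13 adjusted over the list alone; adjusted p = 2.05e-07), with Gadd45b at 1.94, Gadd45g at 1.74 and Rgs2 at 2.51. Of 14 MAP kinase phosphatases and feedback inhibitors, 10 rose and 1 fell (as many adjusted over the list alone; adjusted p = 5.26e-06), among them Dusp1 at 2.02 and Dusp5 at 1.38. The last 2 lists were also called with an estimated correlation, at adjusted p = 0.0391 and adjusted p = 0.0175. Secreted factors and neuropeptides had 9 of 16 higher (10 adjusted over the list alone; adjusted p = 4.29e-05, and adjusted p = 0.129 with an estimated correlation), with Bdnf, Vgf, Nppc and Scg2 named above. The MEF2 family and class IIa histone deacetylases had 4 of 7 higher (4 adjusted over the list alone; adjusted p = 0.02, and adjusted p = 0.0716 with an estimated correlation). Reported MEF2 targets had 11 higher and 2 lower of 14 (as many adjusted over the list alone; adjusted p = 9.03e-06, and adjusted p = 0.0608 with an estimated correlation), led by Bdnf, Nr4a1, Klf4 at 1.44 and the cell adhesion gene Pcdh10 at 1.28, and the same limit on independence holds for this list. Endoplasmic reticulum stress and heat shock genes had 7 higher and 2 lower of 15 (8 and 2 adjusted over the list alone; adjusted p = 0.000538, and adjusted p = 0.087 with an estimated correlation), with Chac1, which breaks down glutathione, up 2.86-fold and Herpud1 2.52-fold. Cholesterol biosynthesis had 6 higher and 1 lower of 13 (7 and 1 adjusted over the list alone; adjusted p = 0.0372, and adjusted p = 0.853 with an estimated correlation), with Sc5d, Insig1 and Cyp51 at 0.74, 0.71 and 0.62 and Nsdhl at -0.59. Its adjusted p was 0.136 without control 6 h replicate 2 and 0.126 without control 0 h replicate 3.

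Other lists had members that moved without a shift of the list at 6 h. Voltage-gated potassium channels had 4 higher and 5 lower of 13 (as many adjusted over the list alone; adjusted p = 0.902, median -0.07 and mean 0.03), with Kcna1 and Kcna4 at 1.04 and 0.94 and the subunit gene Kcnab1 at -0.88, whose other probe set was not called. Voltage-gated sodium and calcium channels had 3 higher and 3 lower of 17 (as many adjusted over the list alone; adjusted p = 0.907), such as Cacnb2 at 0.75 and Cacna1d at -0.79. Among glutamate receptors and excitatory scaffolds, 5 of 25 were higher and 3 lower (5 and 2 adjusted over the list alone; adjusted p = 0.585), with the scaffold genes Dlg2 at 0.56 and Dlg3 at -0.80. Circadian clock genes had 4 higher and 5 lower of 13 (as many adjusted over the list alone; adjusted p = 0.688), the higher ones being Per1, Per2, Cry1 at 0.97 and Cry2 at 0.78. GABA receptors and inhibitory synapse genes had 2 higher of 10 (2 adjusted over the list alone; adjusted p = 0.309), Gad1, which makes GABA, at 0.92 and Gabrb1 at 0.50. Glycolysis and glucose uptake genes had 3 higher and 3 lower of 15 (as many adjusted over the list alone; adjusted p = 0.536), and synaptic vesicle proteins 3 higher and 1 lower of 19 (2 and 1 adjusted over the list alone; adjusted p = 0.585). Markers of astrocytes had 1 higher and 1 lower of 11 (0 adjusted over the list alone; adjusted p = 0.943), markers of oligodendrocyte lineage and of microglia had no member called (adjusted p = 0.688 and 0.943), and pan-neuronal markers had 2 higher and 2 lower of 16 (1 and 2 adjusted over the list alone; adjusted p = 0.789).

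Comparing 6 h with 1 h in the control arm separated late from early genes. Arc had fallen 6.23-fold from its level at 1 h (log2 -2.64, SE 0.12; adjusted p = 1.81e-09), Egr2 4.6-fold, Egr1 3.93-fold and Egr4 2.9-fold, while Fos at -0.51 was not called (adjusted p = 0.289). Among genes that rose from 1 h to 6 h were Bdnf, 5.27-fold (0.99 on the log2 scale by its other probe set), the interleukin 6 receptor gene Il6r, 6.27-fold (SE 0.19), the membrane protein Emp1, 5.84-fold (0.48 by its other probe set), and Rcan2, an inhibitor of calcineurin, 4.52-fold. The matrix gene Ccn2 rose by 2.34 and the transcription factor Klf5 by 2.02 on the log2 scale. Penk, which encodes the enkephalin precursor, rose by 0.95, Gad1 by 1.04 and Hdac5 by 1.26. In total 1641 genes were higher and 2236 lower at 6 h than at 1 h. Secreted factors and neuropeptides had 11 of 16 higher (12 adjusted over the list alone; adjusted p = 2.93e-05, and adjusted p = 0.26 with an estimated correlation), and endoplasmic reticulum stress and heat shock genes had 7 of 15 higher (7 adjusted over the list alone; adjusted p = 0.00552, and adjusted p = 0.26 with an estimated correlation). Immediate early transcription factors split, 8 higher and 11 lower (as many adjusted over the list alone; adjusted p = 0.456, median -0.37). Of the genes higher at 1 h, 121 were also higher at 6 h, where independent lists would share 20.9. For genes lower at both times the count was 119, against 42.0 for independent lists. Across genes, which are not independent replicates, the 1 h and 6 h changes correlated at 0.505 with a covariance of 0.0450. Arrays simulated without any change, those at 0 h included, gave means of 0.499 and 0.00676. They were drawn independently for each gene and array, so they carry no correlation between genes or between arrays of the same number. With 3 control arrays the 0 h group could not be divided, so part of the excess may come from the shared controls. A further 1632 genes were higher and 2663 lower at 6 h without a call at 1 h.

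**Figure D2:**
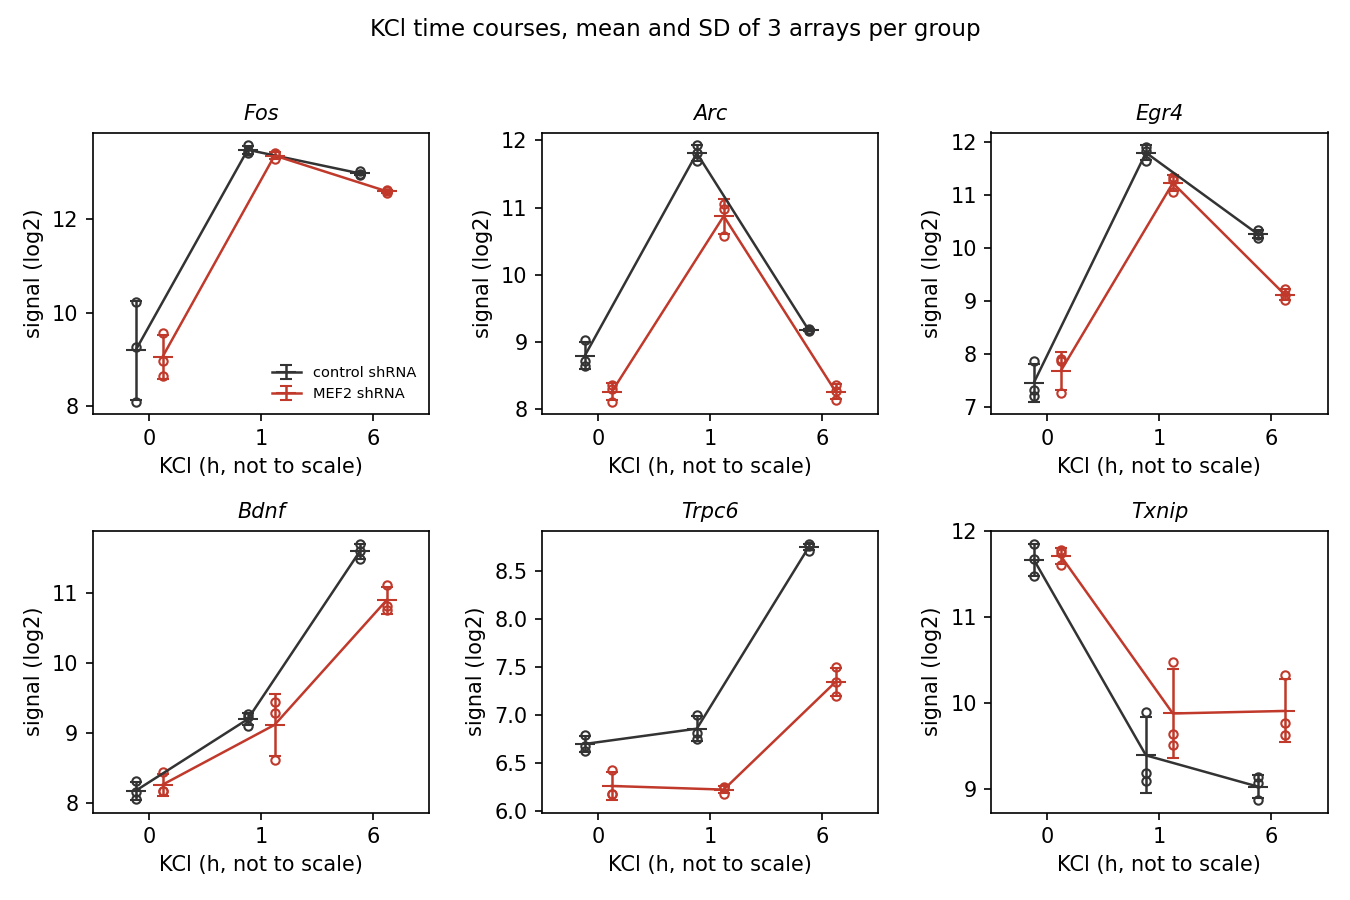
Log2 signal of Fos, Arc, Egr4, Bdnf, Trpc6 and Txnip against hours of KCl in both arms, with points for the 3 arrays of each group and lines through the group means. Mean Arc signal runs from 8.79 to 11.81 to 9.17 in the control arm and from 8.25 to 10.87 to 8.26 in the RNAi arm.

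In neurons kept in the blockers, before any KCl, the arms already differed, which addresses what MEF2 knockdown does at rest. Fam81a was 3.83-fold higher with RNAi (log2 1.94, SE 0.16, n = 3 per group; adjusted p = 1.47e-06), Tmtc1 2.95-fold and Ntrk3, the neurotrophin-3 receptor, 2.89-fold. Dynlt2b, a dynein light chain, was 2.59-fold higher (SE 0.08), the GABA receptor subunit Gabrb1 rose by 0.94, and the p53 target Ccng1 and the cell death gene Hrk rose by 0.87 and 0.92. Apart from Mef2a, lower genes were led by Rimkla, which makes N-acetylaspartylglutamate, at 2.64-fold (log2 -1.40, SE 0.12), the arginine methyltransferase Prmt8 at 2.37-fold and the nuclear receptor Esrrg at 2.36-fold. The neuropeptide Sst was 2.25-fold lower (SE 0.23), the neurofilament Nefm was at -0.97 and Lgi1, a secreted synaptic protein linked to epilepsy, was 1.96-fold lower. Arc was lower by a smaller amount (-0.54, SE 0.12; adjusted p = 0.00672). Fos, Egr1, Nr4a1, Bdnf and Homer1 were not called, with differences of -0.14, 0.12, 0.07, 0.09 and -0.06, although another Homer1 probe set was called higher at 0.80. Of the genes tested, 947 were called higher and 677 lower, and the replicate block called 1733 and 1113, or 2846 in place of 1624. After quantile normalization the calls were 833 higher and 813 lower.

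Cholesterol biosynthesis was the list called at 0 h, with 7 of 13 members lower (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.000313, and adjusted p = 0.786 with an estimated correlation). Insig1, Fdft1 and Nsdhl were at -0.82, -0.56 and -0.52. Glutamate receptors and excitatory scaffolds had 1 higher and 6 lower of 25 (2 and 7 adjusted over the list alone; adjusted p = 0.0532), among them the postsynaptic scaffolds Shank3 and Shank1 at -0.58 and -0.54, the other Shank1 probe sets not being called. This list was called with the replicate block (adjusted p = 0.0229, range over its alternatives 0.00305 to 0.786), and its adjusted p was 0.00305 without control 0 h replicate 1, 0.0499 without RNAi 0 h replicate 2 and 0.0121 without RNAi 0 h replicate 3. Sodium and calcium channels had 3 of 17 lower (5 adjusted over the list alone; adjusted p = 0.107), with Scn3b at -0.62. The block gave an adjusted p of 0.0468 (range 0.0412 to 0.786), and leaving out RNAi 0 h replicate 3 gave 0.0412. Single markers of other cells differed as well, without a call of their lists. The fibroblast genes Lum and Dcn were 2.23-fold and 2.09-fold lower, and 2 of 8 endothelial and fibroblast markers fell (2 adjusted over the list alone; adjusted p = 0.272, median -0.08 and mean -0.24). Astrocyte markers had a median of 0.14 with no member called (adjusted p = 0.203), and were called with the block (adjusted p = 0.0468, range 0.0468 to 0.911).

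After 1 h of KCl the RNAi arm was set against the control arm to see which induced genes depend on MEF2 early. Arc was 1.91-fold lower with RNAi (log2 -0.94, SE 0.12; adjusted p = 8.18e-05), Egr2 2.34-fold lower (log2 -1.23, SE 0.24; adjusted p = 0.00258), Ccn1 at -0.95 (SE 0.22) and Dusp5 at -0.67. Fos, Egr1, Nr4a1, Jun, Bdnf and Homer1 were not called, with differences of -0.12, -0.31, -0.17, -0.07, -0.08 and -0.17, although another Homer1 probe set was called higher at 0.64. The largest differences included those of genes named at 0 h, with Fam81a 3.63-fold higher, Tmtc1 at 1.56 and Ntrk3 at 1.23, and with Esrrg 3.33-fold (log2 -1.74, SE 0.14; adjusted p = 1.09e-06) and Rimkla 3.26-fold lower. Edil3, Acta1 and Prmt8 were at -1.57, -1.56 and -1.51, and Coch, Tppp and Ildr2 at -1.40, -1.35 and -1.31. Calls numbered 872 higher and 997 lower, and 1558 and 1515 with the replicate block, 3073 in place of 1869, while quantile normalization turned the balance to 1053 higher and 963 lower. Glutamate receptors and excitatory scaffolds had 8 of 25 lower (9 adjusted over the list alone; adjusted p = 0.000422, and adjusted p = 0.53 with an estimated correlation), including the presynaptic adhesion gene Nrxn3 at -0.88, Shank1 at -0.70 by 1 of its 3 probe sets, Dlg2 at -0.39 and the kinase subunit Camk2b at -0.31.

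Sodium and calcium channels had 4 of 17 lower at 1 h (4 adjusted over the list alone; adjusted p = 0.032, and adjusted p = 0.645 with an estimated correlation), with Scn3b at -0.78 and Scn2b at -0.56. Their adjusted p was 0.0767 without RNAi 1 h replicate 1, 0.0840 without control 1 h replicate 2 and 0.124 without control 1 h replicate 3. Cholesterol biosynthesis had 1 higher and 3 lower of 13 (as many adjusted over the list alone; adjusted p = 0.032, and adjusted p = 0.684 with an estimated correlation), with Nsdhl at -0.52 and Fdft1 at -0.49, and lost its call without RNAi 1 h replicate 1 (0.0610), control 1 h replicate 2 (0.0840) or RNAi 1 h replicate 3 (0.0779). Immediate early transcription factors had 4 of 25 lower (4 adjusted over the list alone; adjusted p = 0.179), and the adjusted p was 0.0296 without control 1 h replicate 1 and 0.0310 without RNAi 1 h replicate 3. Beside these groups, Lum and Dcn were at -1.34 and -1.04, endothelial and fibroblast markers had a median of -0.27 (adjusted p = 0.0642, and 0.00347 without control 1 h replicate 1), and astrocyte markers had a median of 0.20 (adjusted p = 0.111). The astrocyte list was called with the block (adjusted p = 0.0351, range over its alternatives 0.0296 to 0.777), and its adjusted p was 0.0296 without control 1 h replicate 1 and 0.0491 without RNAi 1 h replicate 2.

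At 6 h of KCl, several induced genes were lower with RNAi. Tchh was 5.21-fold lower (log2 -2.38, SE 0.25, n = 3 per group; adjusted p = 1.83e-05), the deubiquitinase Otud1 2.78-fold (SE 0.15), Rcan2 2.75-fold (SE 0.14, with its other probe set at -0.48) and the calcium-permeable channel Trpc6 2.64-fold (log2 -1.40, SE 0.09; adjusted p = 1.15e-07). Egr4 was 2.2-fold lower (SE 0.17; adjusted p = 0.000334), Arc 1.89-fold (log2 -0.92, SE 0.12; adjusted p = 0.000122) and Bdnf 1.62-fold (log2 -0.70, SE 0.16; adjusted p = 0.00837). Lgi1 was 2.39-fold lower (SE 0.17), the GABA B receptor Gabbr2 2.41-fold, Atf3 and Nppc were at -0.99 and -1.01, and Gadd45b was 1.8-fold lower. Higher genes again included Fam81a, 6.12-fold (log2 2.61, SE 0.16; adjusted p = 9.84e-08, with its other probe sets at 1.04 and 1.80), Tmtc1, 3.47-fold, and Dynlt2b at 1.46, now joined by Arrdc4, 2.69-fold higher (SE 0.13). Fos (-0.38, adjusted p = 0.523) and Jun (0.07) were not called, although another Jun probe set was called higher at 0.27. Fos log2 signals at 6 h did not overlap between arms, at 12.56 to 12.63 with RNAi and 12.96 to 13.03 in controls. Its SE pools all groups, among them the scattered control arrays at 0 h (SD 1.07). Egr1 (-0.63, adjusted p = 0.156), Nr4a1 (-0.64, adjusted p = 0.0802) and Homer1 (-0.19, adjusted p = 0.0605) were not called either, and each was called with the replicate block. Over the alternatives their adjusted p ranged from 0.00683 to 0.384, from 0.00434 to 0.358 and from 0.0430 to 0.231, and was 0.00434 for Nr4a1 without RNAi 6 h replicate 3 and 0.0468 for Homer1 without RNAi 6 h replicate 2. Calls numbered 947 higher and 934 lower, and 1674 and 1407 with the block, 3081 in place of 1881, and 1027 and 948 after quantile normalization. Without RNAi 6 h replicate 1 the count was 1207.

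Immediate early transcription factors had 8 of 25 members lower with RNAi at 6 h (11 adjusted over the list alone), with a median of -0.36 (adjusted p = 0.0011, and adjusted p = 0.473 with an estimated correlation). Reported MEF2 targets had 6 of 14 lower (8 adjusted over the list alone; adjusted p = 0.00444, and adjusted p = 0.473 with an estimated correlation), among them Lgi1, Arc, Bdnf and the protocadherin Pcdh17 at -0.37. As above, members may have been picked on these samples, so that direction is not independent evidence. The MEF2 family and class IIa histone deacetylases had 2 of 7 lower, Mef2a and Mef2d (2 adjusted over the list alone; adjusted p = 0.00847, and adjusted p = 0.176 with an estimated correlation). Both falls are the knockdown described above, so the call of this list is not a separate result. Glutamate receptors and excitatory scaffolds had 1 higher and 7 lower of 25 (as many adjusted over the list alone; adjusted p = 0.000102, and adjusted p = 0.473 with an estimated correlation), with Shank3 at -0.78, Dlg2 at -0.77 (SE 0.09) and Camk2b at -0.36. Sodium and calcium channels had 3 of 17 lower (6 adjusted over the list alone; adjusted p = 0.00444, and adjusted p = 0.473 with an estimated correlation), with Scn3b at -0.76, and the adjusted p was 0.101 without RNAi 6 h replicate 1. Cholesterol biosynthesis had 1 higher and 4 lower of 13 (1 and 5 adjusted over the list alone; adjusted p = 0.00971, and adjusted p = 0.534 with an estimated correlation), with Fdft1 at -0.53, and the adjusted p was 0.0738 without control 6 h replicate 2 and 0.0884 without RNAi 6 h replicate 3. Among cell type markers, the tight junction gene Cldn5 was at -0.97, endothelial and fibroblast markers had a median of -0.11 (adjusted p = 0.188), and astrocyte markers a median of 0.24 (adjusted p = 0.149, called with the block at adjusted p = 0.0308, range 0.0308 to 0.710).

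Averaged over the 3 times, 2288 genes were higher with RNAi and 1819 lower. Fam81a was 4.4-fold higher (log2 2.14, SE 0.09, n = 9 arrays per arm; adjusted p = 2.73e-10) and Rimkla 3.04-fold lower (log2 -1.60, SE 0.07; adjusted p = 2.78e-10). Arc was at -0.80 (SE 0.07; adjusted p = 3.31e-07), Nefm at -1.04, Sst at -0.99, and the transthyretin gene Ttr at 1.26. The differences at the separate times were similar across genes, which are not independent replicates. Pearson correlations were 0.841 between 0 h and 1 h, 0.729 between 0 h and 6 h and 0.793 between 1 h and 6 h, on separate arrays, and 812 genes were called at all 3 times, 416 higher and 395 lower throughout. Arrays of the same replicate number correlated between times, so the 9 arrays of an arm, and the 3 times, are not independent of one another. Glutamate receptors and excitatory scaffolds had 1 higher and 11 lower of 25 (as many adjusted over the list alone; adjusted p = 0.000403), sodium and calcium channels 6 of 17 lower (6 adjusted over the list alone; adjusted p = 0.0107), and cholesterol biosynthesis 1 higher and 8 lower of 13 (1 and 10 adjusted over the list alone; adjusted p = 0.00195). Each of the 3 had adjusted p = 0.433 with an estimated correlation. Immediate early transcription factors had 1 higher and 10 lower of 25 (as many adjusted over the list alone; adjusted p = 0.0372, and adjusted p = 0.62 with an estimated correlation). Their call was lost without control 0 h replicate 1 (0.0589), RNAi 1 h replicate 1 (0.0852), RNAi 6 h replicate 1 (0.0661), control 1 h replicate 2 (0.0648), RNAi 0 h replicate 2 (0.0607), control 1 h replicate 3 (0.0803) or control 6 h replicate 3 (0.0673).

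Cell type markers also differed between arms over the 3 times. Astrocyte markers had 6 of 11 higher, among them S100b at 0.43, Gja1 at 0.34 and Aldoc at 0.30 (6 adjusted over the list alone; camera adjusted p = 0.0784, and 0.0207 with the replicate block, range over the alternatives 0.0207 to 0.663). Endothelial and fibroblast markers had 1 higher and 4 lower of 8, with Dcn at -0.86 and Lum at -0.83 (1 and 4 adjusted over the list alone; adjusted p = 0.0784, and 0.0465 without control 1 h replicate 1). Scored per array, astrocyte markers were 0.18 higher in the RNAi arm (permutation p = 0.0445), endothelial and fibroblast markers at -0.28 (permutation p = 0.00125) and pan-neuronal markers at -0.11 (permutation p = 0.0163). Scores of oligodendrocyte lineage (0.10, permutation p = 0.561) and microglia (0.05, permutation p = 0.36) were not called by this test. These 5 tests were not adjusted for one another. Their permutations treated the arrays of an arm as independent, although arrays of the same replicate number correlated. Pan-neuronal markers as a list had 3 higher and 6 lower of 16 (as many adjusted over the list alone; adjusted p = 0.46), and proliferating and progenitor cell markers 2 higher of 14 (1 adjusted over the list alone; adjusted p = 0.492, and 0.0422 without the 6 arrays of number 1, an alternative added after the data were seen, range over the alternatives 0.0422 to 0.944). Housekeeping controls had 5 of 10 higher, with Hprt1 at 0.42 and Gapdh at 0.11 (5 adjusted over the list alone; adjusted p = 0.0706, and 0.0465 without control 1 h replicate 1). After quantile normalization Hprt1 and Gapdh were at 0.43 and 0.11 and still called. Interferon response genes had 2 of 6 higher (2 adjusted over the list alone; adjusted p = 0.262), potassium channels 1 higher and 5 lower of 13 (1 and 6 adjusted over the list alone; adjusted p = 0.0784), and apoptosis and p53 response genes 4 higher and 1 lower of 10 (as many adjusted over the list alone; adjusted p = 0.0784), the higher ones including Hrk at 0.94 and Ccng1 at 0.85.

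The RNAi arm was also followed over KCl on its own, to show the response that remains with reduced MEF2. At 1 h, Fosb rose 57.1-fold, Fos by 4.32 and Junb by 4.28 on the log2 scale, Egr4 11.6-fold and Arc 6.14-fold, and Txnip was at -1.83. Calls at 1 h were 135 higher and 289 lower under the deposited scaling, and 164 higher and 207 lower after quantile normalization. The replicate block called 216 and 688, or 904 in place of 424, and the count was 276 without RNAi 0 h replicate 2, 230 without RNAi 1 h replicate 2, 253 without RNAi 0 h replicate 3 and 220 without RNAi 1 h replicate 3. Of 25 immediate early transcription factors, 20 rose and 1 fell (as many adjusted over the list alone; adjusted p = 4.66e-54, also called with an estimated correlation). At 6 h, Fosb was 16.9-fold and Bdnf 6.23-fold higher (0.62 on the log2 scale by its other probe set), Serpinb2 at least 10.8-fold higher, Emp1 and Gem at 2.87 and 2.74, while Arc was back at 0.00 (adjusted p = 0.996). Calls at 6 h were 1610 higher and 2766 lower, with the synaptic effectors at 12 of 15 higher (12 adjusted over the list alone; adjusted p = 1.46e-06, and adjusted p = 0.0593 with an estimated correlation).

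Genes both induced by KCl in the control arm and lower with RNAi at the same time are those the series set out to find. At 1 h there were 13, where independent lists would share 11.9 (odds ratio 1.11, Fisher's exact p = 0.648). With induction taken from both arms there were 18 against 23.3 (odds ratio 0.752, Fisher's exact p = 0.272). Egr2, Ccn1, Arc and Dusp5 had the largest differences among them, followed by Egr4 at -0.57 and Ier2 at -0.45, and 10 of the 13 were not called lower or higher at 0 h. Egr4 lost its call in 4 and Ier2 in 3 of the 6 fits without 1 array. The count was 33 with the replicate block, and 7 without control 1 h replicate 1 or without RNAi 1 h replicate 1. At 6 h there were 286, or 16.3% of the 1759 induced genes against 8.54% of all genes lower with RNAi. Independent lists would share 150 (odds ratio 2.55, Fisher's exact p = 2.54e-31). The control 6 h arrays enter both comparisons and could not be divided, so part of the excess may come from the shared controls. Induction taken from both arms weights the RNAi and control arrays at 6 h equally, so the shared arrays do not tie it to the RNAi difference. By that choice the count at 6 h was 291 against 193 (odds ratio 1.84, Fisher's exact p = 3.55e-15). This argues against the shared controls as the whole of the excess. The largest differences were those of Tchh, Otud1, Rcan2, Trpc6, Lgi1, Zdhhc2 at -1.18 and Egr4, and the group held Nppc, Atf3, Arc, Cldn5, Sh3rf1 at -0.91, Kcna4 at -0.90, Errfi1 at -0.74 and Bdnf. Of the 286, 74 were lower by at least 1.5-fold and 10 by at least 2-fold, and 90 were already lower at 0 h while 193 were not called there. The count was 468 with the block and 174 without control 6 h replicate 3. In the other direction, 405 genes were lowered by 6 h of KCl and higher with RNAi, where independent lists would share 241 (odds ratio 2.39, Fisher's exact p = 4.95e-34). With the block this count was 707, and the shared control arrays limit these counts in the same way. With the KCl response taken from both arms, which weights the arms equally, it was 436 against 303 (odds ratio 1.93). At 1 h there were 24 such genes against 13.2 (Fisher's exact p = 0.00351), and 90 with the block. Genes lower both with KCl in the control arm and with RNAi numbered 13 at 1 h (odds ratio 0.850, Fisher's exact p = 0.683) and 249 against 238 at 6 h (Fisher's exact p = 0.388), and 106 against 60.2 and 362 against 299 with the KCl response taken from both arms.

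The interaction asked whether the response to KCl itself differed between arms. At 1 h limma called 0 genes, as it did with the replicate block, while 363 had an unadjusted p under 0.05 and fry called 0 lists. Arc, Jun and Egr1 had interactions of -0.40 (SE 0.17), -0.47 (SE 0.14) and -0.43, each at adjusted p = 1. Without RNAi 1 h replicate 1, 1 gene was called. At 6 h the response of 13 genes differed. Otud1 rose by 2.02 on the log2 scale in the control arm and by 0.66 in the RNAi arm (interaction -1.36, SE 0.22; adjusted p = 0.0281), and Egr4 by 2.79 and 1.43 (interaction -1.36, SE 0.24; adjusted p = 0.0361). Trpc6 rose by 2.05 and 1.08 (interaction -0.97, SE 0.12; adjusted p = 0.00942), and since 2 of its 3 RNAi arrays at 0 h lay at the floor, its rise in the RNAi arm may be understated. The scaffold protein gene Lin7a rose by 1.25 and 0.60, and Dot1l, a histone H3 methyltransferase, by 1.12 and 0.43. Sh3rf1, a ubiquitin ligase scaffold of JNK signalling, rose by 2.40 and 1.56, and Mxi1, an antagonist of Myc, by 1.01 and 0.52, with its other probe set not called. Mia2, Smad7 and Micu3 also had lower responses in the RNAi arm, with interactions of -0.56, -0.74 and -0.83. Arrdc4, Pdlim1 and Sdhaf3 went the other way, with Arrdc4 at -2.72 in the control arm and -1.64 in the RNAi arm. Some of the 13 already differed between arms at 0 h. Micu3, Dot1l and Mia2 were called higher with RNAi there, at 1.04, 0.41 and 0.27, and Pdlim1 and Trpc6 lower, at -0.70 and -0.44. Micu3 was not called after 6 h of KCl in the control arm (0.18, adjusted p = 0.181). Bdnf had an interaction of -0.78 (SE 0.23; adjusted p = 0.264), Arc of -0.38 (adjusted p = 0.585) and Fos of -0.24, none of them called. An unadjusted p under 0.05 was found for 900 genes, and the block called 126, 40 higher and 86 lower.

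Single arrays weighed on this count. It was 8 without control 6 h replicate 1, 6 without RNAi 0 h replicate 1, 7 without RNAi 6 h replicate 1, 2 without control 0 h replicate 2, 4 without control 6 h replicate 2, 6 without RNAi 0 h replicate 2, 3 without control 0 h replicate 3, 1 without control 6 h replicate 3, 2 without RNAi 0 h replicate 3 and 5 without RNAi 6 h replicate 3. Trpc6 was called in each of the 12 fits without 1 array, Dot1l lost its call in 3 of them, Lin7a in 5, and the other 10 genes in 8 to 11. Immediate early transcription factors had a lower response as a list (median -0.24, 1 of 25 lower and 2 adjusted over the list alone; adjusted p = 0.0139, and adjusted p = 0.955 with an estimated correlation). Reported MEF2 targets had a median of -0.26, with no member called over all genes and 2 of 14 lower adjusted over the list alone (adjusted p = 0.0157, and adjusted p = 0.732 with an estimated correlation). Glutamate receptors and excitatory scaffolds had a median of -0.14, with 1 of 25 lower adjusted over the list alone (adjusted p = 0.0458, and adjusted p = 0.955 with an estimated correlation), and were not called with the block (adjusted p = 0.068, range 0.00318 to 0.955). The immediate early list lost its call without RNAi 0 h replicate 1 (0.0610), RNAi 6 h replicate 1 (0.170), control 0 h replicate 3 (0.109) or control 6 h replicate 3 (0.0561). The target list lost it without RNAi 6 h replicate 1 (0.187), control 6 h replicate 3 (0.0561) or RNAi 0 h replicate 3 (0.0770). The glutamate list lost it without control 0 h replicate 1 (0.467), RNAi 6 h replicate 1 (0.521), RNAi 0 h replicate 2 (0.0806), control 6 h replicate 3 (0.0983) or RNAi 0 h replicate 3 (0.325).

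**Figure D3:**
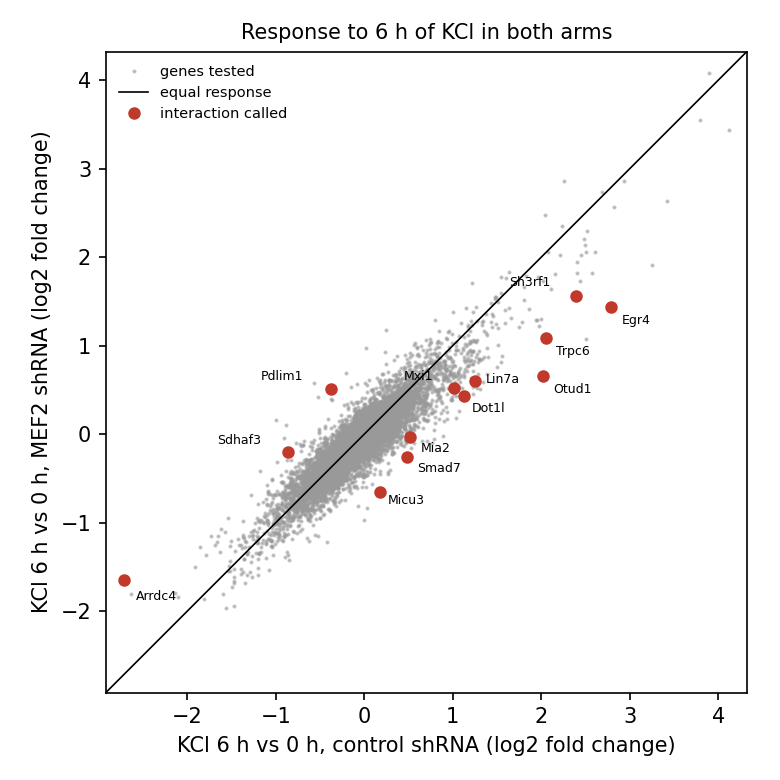
Log2 fold change after 6 h of KCl in the RNAi arm against that in the control arm, 1 point per gene tested, with the line of equal response. Red points are the 13 genes whose response differed between arms at adjusted p under 0.05, such as Otud1 at 2.02 in the control arm and 0.66 in the RNAi arm.

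Across the induced genes as a set, the response at 6 h was slightly smaller with RNAi. Of 2262 genes induced over both arms, 58.8% rose less in the RNAi arm, with median log2 changes of 0.38 in the control arm and 0.32 in the RNAi arm (camera p = 0.00122, and p = 0.137 with an estimated correlation). Among the 138 genes induced at least 2-fold, such as Fos, Bdnf and Nr4a1, 75.4% rose less, with medians of 1.38 and 1.23 (camera p = 8.33e-13, and p = 0.0624 with an estimated correlation). For the 255 genes induced at 1 h, 55.3% rose less (camera p = 0.646, and p = 0.885 with an estimated correlation), and for the 38 among them that rose at least 2-fold, 60.5% did, although their median was 2.03 in the control arm and 2.18 in the RNAi arm (camera p = 0.0400, and p = 0.499 with an estimated correlation). The share of genes induced at 1 h that rose less was 39.5% without RNAi 1 h replicate 1 and 67.0% without control 0 h replicate 1.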

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

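No test in this part was chosen after its result was seen. The test of the difference between arms found 13 genes whose response to 6 h of KCl differed. Their interactions on the log2 scale were 1.08 for Arrdc4, 0.88 for Pdlim1 and 0.65 for Sdhaf3, and, in the direction of a smaller or more negative response with RNAi, -0.495 for Mxi1, -0.56 for Mia2, -0.65 for Lin7a, -0.69 for Dot1l, -0.74 for Smad7, -0.83 for Micu3 and for Sh3rf1, -0.97 for Trpc6, and -1.36 for Egr4 and for Otud1. The same test found lower responses with RNAi for immediate early transcription factors (median -0.24), reported MEF2 targets (median -0.26) and glutamate receptors and excitatory scaffolds (median -0.14), none of them called with an estimated correlation. Of 100 rearrangements of the arms within each KCl time, the real one included, 2 gave 13 or more genes. That share is under 0.05, but the rearrangements took no account of the replicate numbers, whose arrays correlate. The count also fell to 1 without control 6 h replicate 3, so chance is not excluded for these genes. The highest other rearrangement called 113 genes, several times the real count, which points to a structure of the samples whose source was not tested. At 1 h limma called 0 genes for the interaction (363 had an unadjusted p under 0.05), so that 100 of 100 rearrangements gave as many by construction and the test says nothing there. The highest other gave 55.

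The other counts were set against rearrangements in the same way. For RNAi against control averaged over times, 1 of 100 gave as many as the real 4107 genes, and the highest other gave 983. For genes induced by KCl and lower with RNAi, 4 of 100 draws gave as many as the real 13 at 1 h, with 542 as the highest other, and 3 of 100 gave as many as the real 286 at 6 h, with 2122 as the highest other. For the averaged comparison the share was under 0.05. The rearrangements took no account of the replicate numbers, whose arrays correlate, so they do not by themselves exclude chance. For the counts of induced genes the shares decide nothing, since the draws mix KCl groups and so remove the response itself. Those draws do not judge the overlap, which at 1 h was no more than independent lists would share (13 against 11.9). The draws that call several times the real count point to a structure of the samples, and since they keep 7 of 9 arrays with their group, the real groups trading roles can be that structure. The 8 comparisons of 3 arrays with 3 have 10 splits each, too few for a share under 0.05, and in each only 1 split, the real one, gave as many genes. The real counts and the highest of the other splits were 295 and 1 for control 1 h against 0 h, 4542 and 0 for control 6 h against 0 h, 3877 and 0 for control 6 h against 1 h, 1624 and 1 for RNAi at 0 h, 1869 and 0 for RNAi at 1 h, 1881 and 1 for RNAi at 6 h, 424 and 0 for the RNAi arm at 1 h, and 4376 and 0 for the RNAi arm at 6 h. Splits that part every pair of like-numbered arrays, as the real one does, called 0 genes, and those that keep a pair together called at most 1.

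Signal was also found in probe sets that the platform annotation lists with no gene or with several gene symbols, which no comparison above uses. Of 4832 such probe sets above the filter, 62 were called after 1 h of KCl in the control arm (40 higher and 22 lower), 1588 after 6 h (625 higher and 963 lower) and 1519 for RNAi averaged over times (638 higher and 881 lower).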

How the results depend on the processing

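The comparisons, lists, model and other settings were fixed before the data were examined, except leaving out the 6 arrays of number 1, which was chosen only after the results were seen, and the later tests and list named as such with the patterns weighed. No named gene or list called in the comparisons above reversed its direction under an alternative. The alternative with all probe sets was not applied to named genes or lists. Other probe sets of some named genes were called the opposite way, such as that of Arpp21 after 6 h of KCl in the control arm (1.41 against -1.73). Of 11049 values of named genes under alternatives other than single arrays left out, 10550 kept their side of the threshold, 217 lost a call and 282 gained one. Of 10260 with 1 array left out, 9702 kept it, 486 lost a call and 72 gained one. For the lists these numbers were 2709, 72 and 99 of 2880, and 2053, 42 and 65 of 2160. Leaving out arrays lowers the power of a test by construction, and beyond that the cause of the changes was not tested. Genes near the floor of 72.6 have understated folds.

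With 1 array left out, genes called ranged from 188 to 269 for control 1 h against 0 h, 1207 to 1635 for RNAi at 6 h, 220 to 376 for the RNAi arm at 1 h, 0 to 1 for the interaction at 1 h and 1 to 15 at 6 h. Genes induced and lower with RNAi ranged from 7 to 16 at 1 h and 174 to 301 at 6 h, and the share of induced genes rising less with RNAi at 1 h from 39.5% to 67.0%. Lists called ranged from 1 to 3 for RNAi at 0 h, 1 to 8 for RNAi at 1 h, 0 to 5 for the interaction at 1 h and 0 to 4 at 6 h.

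With the replicate block, genes called became 601 for control 1 h against 0 h, 2846, 3073 and 3081 for RNAi at 0, 1 and 6 h, 904 for the RNAi arm at 1 h, 126 for the interaction at 6 h, and 33 and 468 for genes induced and lower at 1 h and 6 h. Lists called became 4 for RNAi at 0 h and 2 for the interaction at 1 h. Among named genes the block lost 0 calls of limma and gained 106. Beyond the calls named with the results, it called proliferating and progenitor cell markers after 1 h of KCl in both arms and after 6 h in the control arm, and cholesterol biosynthesis and glycolysis for the interaction at 1 h, and it changed no other list's call. Array weights, which put 0.362 to 0.639 on arrays of number 1, gave 488 genes for control 1 h against 0 h, 2831 for RNAi at 0 h, 1209 for the RNAi arm at 1 h and 83 for the interaction at 6 h. They called 2 lists for RNAi at 0 h, 7 for RNAi at 1 h and 0 for the interaction at 6 h. Fitting only the groups compared gave 125 genes for control 1 h against 0 h, 979 for RNAi at 0 h, 262 for the RNAi arm at 1 h, 2 for the interaction at 6 h and 8 induced and lower at 1 h, with 2 lists for RNAi at 0 h and 6 at 1 h.

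Lists called also moved with quantile normalization (5 for RNAi at 1 h, 2 for the interaction at 1 h), no filter (2 for RNAi at 0 h, 5 at 1 h), the stricter filter (3 for RNAi at 0 h, 1 at 1 h, 2 for the interaction at 1 h), and the intensity trend with robust prior (2 for RNAi at 0 h, 3 for the interaction at 1 h). With all probe sets tested, 23 genes were induced and lower at 1 h. Taking induction from the control arm alone, which selects on arrays that enter the difference, the share rising less with RNAi was 70.8% at 1 h and 73.7% at 6 h. With an estimated correlation, camera called 4 lists for control 1 h against 0 h, 2 for 6 h against 0 h and 0 for 6 h against 1 h, 0 for RNAi at 0 h, 0 at 1 h, 0 at 6 h and 0 averaged, 4 and 1 for the RNAi arm at 1 h and 6 h, and 0 for the interaction at 6 h. Fry called 4 for control 6 h against 1 h, 5 for RNAi at 0 h, 7 at 1 h, 13 averaged and 0 for the interaction at 6 h. Without the 6 arrays of number 1, the interaction called 2 genes at 1 h and 23 at 6 h, and lists called were 3 for RNAi at 0 h, 6 at 1 h, 8 averaged and 1 for the interaction at 6 h.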

Other observations

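The zinc-finger list was made after such genes were seen among the falls at 1 h, and its test in the RNAi arm, the count of genes without marked probe sets and the tests of cell type scores and RNA quality were chosen only after the results they bear on were seen. Single genes of 3 lists that were not called differed between arms averaged over times. The neuropeptide genes Npy and Tac1, found in subsets of neurons, were lower with RNAi, at -0.79 and -0.76 on the log2 scale (SE 0.14 each), as was Sst, given above. The vesicular GABA transporter Slc32a1 was at -0.58 and the receptor subunit Gabra2 at -0.83, while Gabrb1 was 1.75-fold higher and Gad1, at 0.03 (adjusted p = 0.803), was not called. The vesicular glutamate transporter Slc17a7 was at -0.60, and Cplx1, which regulates vesicle fusion, was 1.51-fold higher. By list, where 37.6% of all genes were called, secreted factors and neuropeptides had 2 higher and 5 lower of 16 (as many adjusted over the list alone; adjusted p = 0.262), GABA receptors and inhibitory synapse genes 1 higher and 4 lower of 10 (as many adjusted over the list alone; adjusted p = 0.481), and synaptic vesicle proteins 4 higher and 5 lower of 19 (as many adjusted over the list alone; adjusted p = 0.927).

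Homer1 probe sets split by response. The probe set with the largest change at 6 h rose by 3.39 on the log2 scale after 6 h of KCl in the control arm and by 2.49 in the RNAi arm, and was higher with RNAi at 0 h (0.80, SE 0.12; adjusted p = 0.000448 over all probe sets) and at 1 h (0.64; adjusted p = 0.00217). A further probe set rose by 3.10 at 1 h and at 6 h in the control arm, and by 2.33 and 2.49 in the RNAi arm. The other 3 changed by at most 0.30 in the control arm. Which transcripts each probe set reads is not given in the sources used here.

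A stronger split was seen in 104 genes with probe sets called in opposite directions after 6 h of KCl in the control arm, led by Arpp21 (1.41 and -1.73), Baiap2 (1.89 and -0.75) and Pnisr (1.35 and -1.03). Genes with more than 1 probe set above the filter numbered 2874. Against a chance difference between the probe sets, that difference had the same sign in the RNAi arm, on separate arrays, in 100% of the genes (95% exact interval 96.5% to 100%, and 91.4% to 100% allowing for correlation between genes). The sign also recurs where only 1 probe set moves, so a chance call of the other is not excluded. Most pairs moved in opposite directions in the RNAi arm, but some moved the same way, such as those of Rbm39 (-0.08 and -0.59) and Syn2 (0.09 and 0.02). Against dim probe sets, 73.1% of the genes had both probe sets above the stricter filter (63.5% to 81.3%). Probe sets marked as matching several transcripts are not the cause in 88 genes, which hold none, and stay open for the other 16, since the odds ratio of holding one was 1.09 with an interval of 0.589 to 1.89. Transcripts of the same gene that respond in opposite ways may therefore be present, a hypothesis that the positions of the probes, not used here, would test.

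Genes with zinc-finger symbols (Zfp or Znf) were a further pattern, for which no biological explanation was tested. Of 189 tested, 37 were lower and 1 higher after 1 h of KCl in the control arm, with a median of -0.12, led by Zfp157, Zfp764l1 and Zfp12. In the RNAi arm 79.4% of these genes had a negative change, and 42 were called lower and 1 higher, against 289 lower of all genes. Camera with an estimated correlation of 0.113 gave p = 0.0252 there. The interval of the share was 72.9% to 84.9% for independent genes. It reaches down to 46.2% allowing for that correlation, so the share alone does not exclude chance. The camera result and the 42 of 189 genes called lower, on arrays separate from those where the list was found, argue against chance for the list. Arrays of the same replicate number correlated between the arms, so the arms are not fully independent. Genes of like brightness shifted less, since 0% of 10000 random lists matched on mean signal had a median as low in the control arm, where the list was found, or in the RNAi arm (list median -0.16, central 90% of the random lists -0.0568 to -0.0157), although these lists do not carry the correlation.

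The differences between arms shared by the 3 KCl times were the last pattern weighed. A lower share of neurons in the RNAi cultures, if the only shift of cell types, would raise the markers of every other cell type alike. Against that alone, the astrocyte score minus the endothelial and fibroblast score differed between arms by 0.458 (95% interval 0.152 to 0.764; permutation p = 0.00525), as the former rose and the latter fell. The pan-neuronal score was itself lower with RNAi (-0.11, permutation p = 0.0163), so a lower share of neurons together with a shift in other cells stays open. Each score is a mean over its list's members, so a few genes can carry it, such as Nefm, Dcn and Lum, all lower with RNAi. Some pan-neuronal markers were called higher, so the scores need not reflect shares of cells. The permutations took no account of the replicate numbers. A difference in RNA quality stays open, since the 3' minus 5' signal of Gapdh differed by -0.0252 (interval -0.0996 to 0.0491; permutation p = 0.452) and that of actin by -0.00445 (permutation p = 0.925), which do not exclude a small one. Loss of MEF2, a shift in neuronal, glial or fibroblast number and effects of the shRNAs on other transcripts could each contribute, and these cannot be told apart with 1 RNAi group.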
